A study of Cricetulus griseus with 6 samples.

How the data were processed

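The samples were 6 suspension cultures of CHO-K1, a line derived from Chinese hamster ovary, each hybridised to its own Affymetrix whole-transcript expression array. Per the labels, 3 flasks held serum-free medium with 1 mg/l putrescine and 3 the same medium without putrescine. Each culture was seeded at 200000 cells/ml in 50 ml, shaken at 170 rpm at 37 °C with 5% CO2 and 80% humidity, and sampled on day 3. RNA came from 4000000 cells, and 300 ng of total RNA was converted into biotin-labelled cRNA with the GeneChip WT PLUS kit, per the labels' protocols. The labels call the flasks of each group biological triplicates, and no replicate was pooled. No batch, slide or scan date was given in the sources used here.

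The deposited table holds 1 log2 value for each probe set and array. Per the submitters' processing notes, the authors used Transcriptome Analysis Console; its version, settings and summarisation method are not given in the sources used here. The log base is not stated either: the values ran from 1.55 to 13.66 with 2 decimals, the span of log2 array intensities, and every fold printed here assumes base 2. The values looked normalized between arrays, with medians between 4.92 and 4.98 and upper quartiles between 7.75 and 7.81. Such scaling would hide any change in total RNA per cell, so differences are relative to the typical probe set. The table had 29700 probe sets and 1 missing value. It marked no control probe sets by name, so none could be removed.

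Gene symbols came from the platform annotation: 16481 probe sets had 1 symbol, 793 had several and 12426 had none, and only probe sets with 1 symbol were named. Symbols were checked by Entrez identifier against the RefSeq gene table of the CriGri-PICRH-1.0 assembly. Of the single-symbol probe sets 16394 matched, and 0 symbols needed updating. The genome build behind the array design was not given in the sources used here, so no coordinates are reported. A gene with several probe sets was represented in the gene lists by the probe set with the highest mean over the 6 arrays. Of 1406 such genes, 362 had more than 1 probe set past the threshold, and 6 of these had probe sets that moved in opposite directions.

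All tests used limma 3.58.1 in R 4.3.3. A linear model with group as its only term was fitted to the deposited log2 values with lmFit, followed by eBayes with default settings (prior degrees of freedom 4.58). Tests were two-sided, and p-values were adjusted over all probe sets by the Benjamini-Hochberg method with a threshold of 0.05 and no minimum fold. Differences are given as without minus with putrescine, on the log2 scale, with the standard error of the moderated fit. No detection p-value was used here, so dim probe sets were judged by level. The number of arrays, 3 per group, limits the precision of every value.

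The text examined 28 gene lists, fixed with the tests of genes and lists and most alternatives before the data were examined. They cover polyamine synthesis, catabolism and transport; arginine, ornithine and proline metabolism; methionine and S-adenosylmethionine metabolism; DNA replication machinery, G1/S regulators, CDK inhibitors, G2/M and mitosis, DNA damage and repair, p53 targets and nucleotide synthesis. Stress lists cover the amino acid response and ATF4 targets, endoplasmic reticulum chaperones and the unfolded protein response, cytosolic heat shock proteins, and NRF2 targets. Metabolic lists cover cholesterol, fatty acids, glycolysis with hypoxia-responsive genes, and oxidative phosphorylation. The rest are ribosome biogenesis, translation factors, apoptosis, autophagy and lysosome, extracellular matrix, immediate early genes, interferon-stimulated genes, N-glycosylation, reference genes, and markers of other tissues. Of 976 list entries, 768 were measured. For each list, members past the threshold were counted over all probe sets and adjusted over the list alone, and limma camera compared the list with the 14899 genes measured, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera was repeated with a correlation estimated from the data, and fry was run on the same lists. With an estimated correlation camera also uses only the residual degrees of freedom of the fit, so this setting changes more than the correlation.

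Genes were named by a fixed rule. It takes the 10 largest rises and 10 largest falls among single-symbol probe sets that passed the threshold without overlap between the groups, a core of polyamine genes whatever their result, and up to 4 members with the smallest p in each list. In the lists that camera called, members past the threshold that went against the list were also named. Where a list had 5 or fewer members past the threshold in a direction, the remaining ones were named too. Those extra names, the remaining polyamine list members that rose, and Klhl24 and Ccng2 in the closing section were chosen after their values were seen. The list of other FOXO-responsive genes in the closing section was written after the data were examined but before the values of its members were looked at.

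The procedure was tested on simulated data for this comparison, with 200 of 29699 probe sets changed. It recovered 43.3% of changes of 0.5 on the log2 scale, 91% of changes of 1 and 98.5% of changes of 2. There were 0 false calls with no change simulated and 6 with 200 changed, 3.7% of the calls. In the list test, a shift of 0.4 in 1 list was recovered and 0 other lists were called. The simulated probe sets varied independently, so the list test does not show how camera behaves with correlated genes. Far fewer probe sets were changed than the 24.4% called in the data, so recovery and the share of false calls may differ there.

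Alternatives were the replicate number as a block, quantile normalization, median centring, leaving out the dimmest 25% of probe sets, and keeping only probe sets above 3.82, the median level of the other-tissue markers. Further ones were 1 probe set per gene, a trended and robust variance, array weights, each array left out in turn, and other thresholds and tests. For the lists, the mean of all probe sets of a gene was also tried.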

Results

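The experiment asked how gene expression in CHO-K1 cells responds when polyamine supply is removed. CHO-K1, a Chinese hamster ovary line used for protein production, is known to lack arginase activity, so that it depends on supplied polyamines or ornithine. On day 3, RNA from 3 cultures with 1 mg/l putrescine and 3 without was measured on 6 arrays with 29700 probe sets. Arrays of the same group correlated more closely (Pearson r across probe sets 0.9957 to 0.9962) than arrays of different groups (0.9856 to 0.9878). The median absolute log2 difference was 0.12 to 0.14 within groups and 0.21 to 0.22 between them.

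Without putrescine, the transferrin receptor gene Tfrc showed the largest rise among the named genes and the stress-induced pseudokinase gene Trib3 the largest fall. Tfrc (probe set 18109090), which mediates iron uptake, was higher by 2.81 on the log2 scale (SE 0.11), at 9.17 ± 0.08 against 6.36 ± 0.17 (SD, n = 3; limma adjusted p = 1.16e-05). Thbs1, which encodes the matrix glycoprotein thrombospondin, was 6.85-fold higher (log2 difference 2.78, SE 0.19), and Ackr3, an atypical chemokine receptor, 6.19-fold higher. Trib3 (probe set 17981768) was 8.06-fold lower, at 7.49 ± 0.17 without and 10.50 ± 0.06 with putrescine (SD, n = 3; limma adjusted p = 1.13e-05). The glycine transporter gene Slc6a9 was 6.77-fold lower, the GTP-binding protein gene Gtpbp2 6.51-fold lower and the glutathione-degrading enzyme gene Chac1 5.97-fold lower.

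The other large rises were in Chst2 (4.18-fold), Znf483 (4.10-fold), Arhgef16 (3.91-fold), Rab7b (3.84-fold), Rnft2 (3.83-fold), Slc17a6 (3.74-fold) and E2f8 (3.51-fold). A further probe set of Rab7b rose by 1.90 on the log2 scale. Slc17a6, a vesicular glutamate transporter gene, was near the level of the other-tissue markers with putrescine (3.87 ± 0.14) and varied widely without it (5.77 ± 0.73, SD, n = 3). The other large falls were in Tbc1d2 (7.82-fold), the lysosomal glycoprotein gene Cd68 (7.14-fold), Ypel3 (6.62-fold), the lipid hydrolase gene Abhd6 (5.62-fold), Extl1 (5.54-fold) and the transcription factor gene Atf3 (5.41-fold). A further probe set of Atf3 fell by 1.99.

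**Figure D1:**
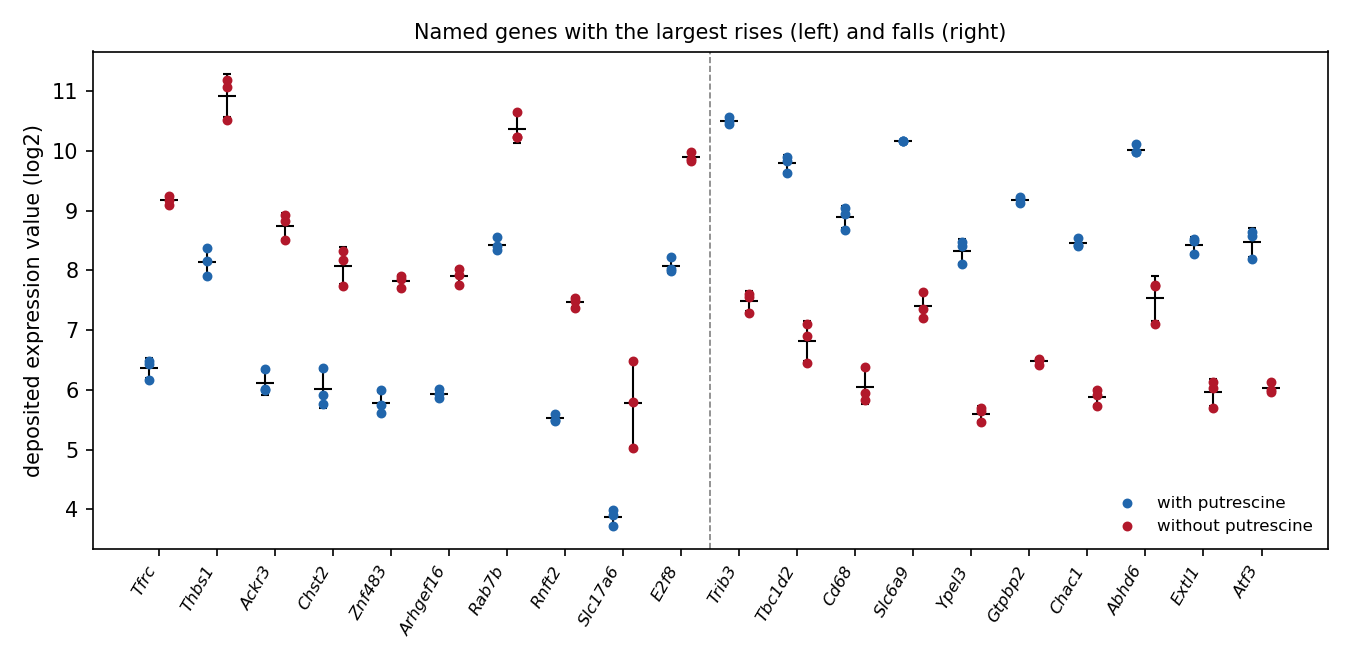
Deposited log2 expression value of each array for the 10 named genes with the largest rises (left of the dashed line) and the 10 with the largest falls (right), blue with and red without putrescine. Points are single cultures, horizontal ticks are group means and vertical bars the SD (n = 3); for Tfrc the means are 6.36 with and 9.17 without putrescine.

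Over the whole array, 7240 probe sets (24.4%) differed between the groups in limma at a Benjamini-Hochberg adjusted threshold of 0.05, 3915 higher and 3325 lower without putrescine. At the level of genes, 2189 named genes had a probe set that rose and 1989 a probe set that fell. Of the probe sets that differed, 789 changed at least 2-fold, 378 upward and 411 downward, and 3115 changed at least 1.5-fold. The groups did not overlap for 37.5% of all probe sets, where chance gives 10%, and for 99.7% of those called. The median log2 difference of all probe sets was 0.007.

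In the polyamine pathway, Odc1 and Sat1 moved in opposite directions. Odc1 (probe set 17996841), which encodes the decarboxylase that makes putrescine from ornithine, rose 2.43-fold without putrescine, from 8.49 ± 0.07 to 9.77 ± 0.04 (SD, n = 3; limma adjusted p = 3.72e-05). Sat1 (probe set 17981703), which encodes the acetyltransferase that starts polyamine breakdown and export, was 3.39-fold lower, at 8.11 ± 0.17 against 9.87 ± 0.06 (SD, n = 3; limma adjusted p = 2.83e-05). Azin1, an antizyme inhibitor that protects ornithine decarboxylase, rose 1.77-fold (log2 difference 0.83, SE 0.08), and Oaz2, an antizyme that promotes its degradation, was 1.98-fold lower. Eif5a2, whose product carries the spermidine-derived residue hypusine, rose 2.39-fold.

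Smaller or unresolved differences were seen at the other genes of the polyamine core. The spermine oxidase gene Smox, at 5.24 with putrescine, was 1.48-fold lower (adjusted p = 0.016). Without with-putrescine replicate 1 its adjusted p was 0.055, in a range of 0.00944 to 0.055 over the alternatives. The polyamine transporter gene Atp13a3 was 1.27-fold higher (adjusted p = 0.0342). This call was lost after quantile normalization and in 5 of the 6 fits with 1 array left out, all but the fit without no-putrescine replicate 1, with adjusted p from 0.00551 to 0.115 over the alternatives. Sms, the spermine synthase gene, had a log2 difference of 0.29 (adjusted p = 0.0692, 0.0154 to 0.187 over the alternatives). Paox, a polyamine oxidase gene, had -0.22 (adjusted p = 0.08, 0.0286 to 0.188). The spermidine synthase gene Srm did not pass the test (adjusted p = 0.745, 0.429 to 0.971). Both arginase genes were below the median level of the other-tissue markers, Arg1 at 3.14 and Arg2 at 2.57 with putrescine, and neither passed the test. Oaz1 and Amd1 had no probe set that could be named here.

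Of the 24 measured members of the polyamine list, 8 rose, 5 fell and 11 did not pass the test, and 10 rose and 6 fell when adjusted over the list alone. Besides Odc1, Eif5a2, Azin1 and Atp13a3, the members that rose were Gpc1, Mtap (0.63), Dhps (0.45) and Cav1 (0.37). Gpc1 was 2.19-fold higher (limma adjusted p = 0.00048). Gpc1, Dhps and Cav1 were not followed over the alternatives. Besides Sat1, Oaz2 and Smox, the members that fell were Slc3a2 (-0.55) and the vesicular polyamine transporter gene Slc18b1 (-0.52). The list as a whole was not called by camera (median log2 difference 0.11; adjusted p = 0.417).

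**Figure D2:**
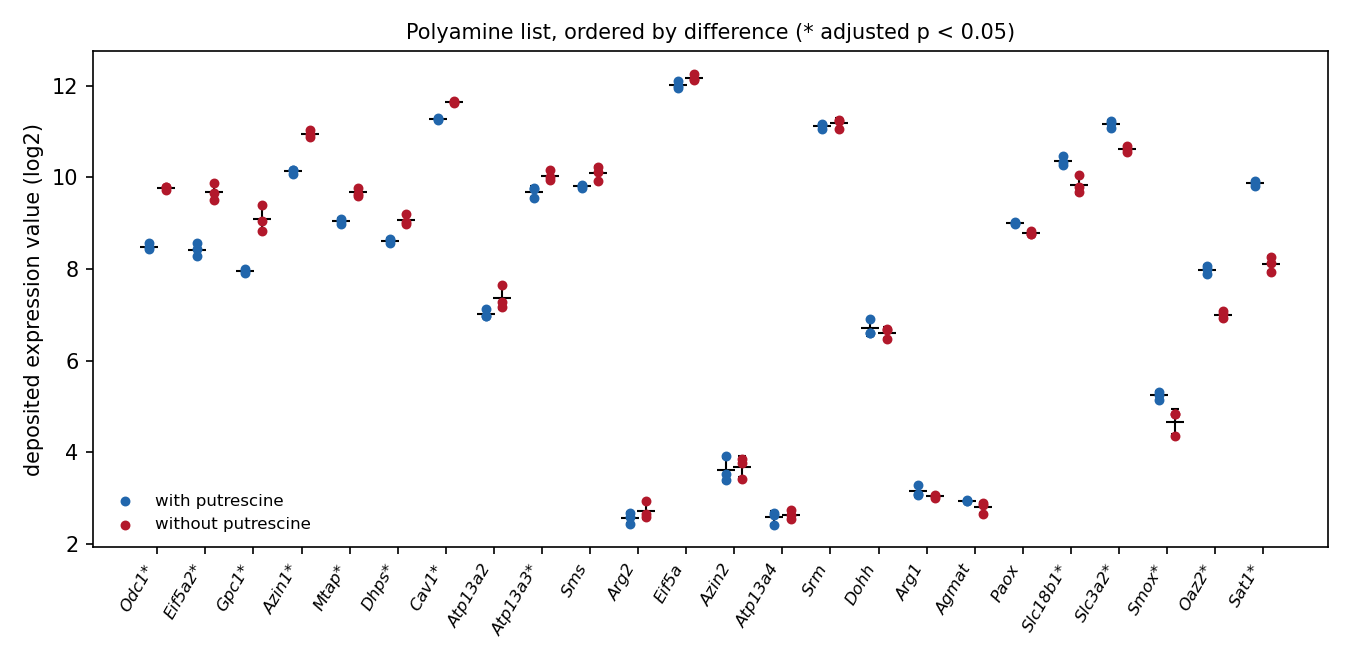
Deposited log2 expression value of each array for the 24 measured members of the polyamine list, ordered from the largest rise to the largest fall, blue with and red without putrescine. Points are single cultures, ticks are means, bars are the SD (n = 3), and an asterisk marks adjusted p under 0.05; Odc1 rose by 1.28 and Sat1 fell by 1.76 on the log2 scale.

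The neighbouring amino acid lists moved in mixed directions. In arginine, ornithine and proline metabolism, 4 of 19 members rose, 3 fell and 12 did not pass, and the counts were 4 and 3 adjusted over the list alone. Pycr1, which makes proline, was 3.29-fold lower, and a further probe set of it fell by 1.26. The arginine transporter gene Slc7a1 was 1.69-fold lower and Asl had -0.57. Aldh18a1, which acts upstream in proline synthesis, rose from 3.60, below the other-tissue marker level of 3.82, to 4.39. Oat, ornithine aminotransferase, rose 1.47-fold, Aldh4a1 had 0.76 and Slc25a15 had 0.35. The call of Slc25a15 was lost in 5 of 6 fits with 1 array left out, all but the fit without with-putrescine replicate 3 (adjusted p 0.0185 to 0.0947 over the alternatives). The list's median (-0.01) and mean (-0.03) were below 0 while camera pointed upward, with adjusted p = 0.992. In methionine metabolism, 4 of 15 members rose, 2 fell and 9 did not pass (5 and 2 adjusted over the list alone; median 0.19; camera adjusted p = 0.223). The methionine salvage gene Apip rose 1.71-fold and Got1 1.52-fold, Mtap, of the same salvage pathway as Apip, rose by 0.63 on the log2 scale and Ahcy by 0.52, while the methionine synthase gene Mtr (-0.46) and Ahcyl1 (-0.37) fell.

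Genes of DNA replication, the G1/S transition and mitosis rose together without putrescine. Of 50 replication genes 35 rose, 1 fell and 14 did not pass (38 and 1 adjusted over the list alone), with a median log2 difference of 0.43. Examples were Dna2, a nuclease-helicase of the replication fork (3.01-fold), Mcm10 (2.87-fold), the checkpoint mediator gene Clspn (2.83-fold) and Mcm3 (2.43-fold). The origin recognition gene Orc3 fell by 0.69. Of 56 G2/M and mitosis genes 47 rose, 0 fell and 9 did not pass (50 and 0 adjusted over the list alone), with a median of 0.58. The mitotic kinase gene Pbk rose 2.57-fold, the kinetochore gene Nuf2 2.35-fold, the spindle checkpoint gene Mad2l1 2.30-fold and Cdca8 2.03-fold. Of the 24 G1/S regulators 17 rose, 2 fell and 5 did not pass, with the same counts adjusted over the list alone and a median of 0.65. E2f8 and E2f7, which repress E2F targets, rose 3.51-fold and 2.03-fold. Ccne2, cyclin E2, rose 3.17-fold, by 0.81 on the log2 scale in a further probe set, and Tfdp1, the dimerisation partner of E2F factors, rose 2.83-fold. The members that fell were Ccnd2 (-0.57) and Rb1 (-0.58). Camera called all of these lists higher, with adjusted p = 1.44e-11 for replication, 4.95e-19 for G2/M and 6.51e-07 for G1/S. With an estimated correlation the calls were lost, at adjusted p = 0.103, 0.103 and 0.0734 in the same order. The estimated correlation of the G1/S list was -0.009, below the preset 0.01, so a stronger correlation did not end that call.

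In the DNA damage and repair list, which camera called higher, 20 of 37 members rose, 0 fell and 17 did not pass, or 21 and 3 adjusted over the list alone (median 0.38; camera adjusted p = 6.88e-06, and adjusted p = 0.181 with an estimated correlation). The recombination gene Rad51ap1 rose 3.02-fold, Exo1 2.32-fold, Brip1 2.06-fold and the DNA polymerase theta gene Polq 2.05-fold. In nucleotide synthesis, also called higher, 13 of 27 members rose, 2 fell and 12 did not pass (15 and 2 adjusted over the list alone; median 0.25; camera adjusted p = 0.00129, and adjusted p = 0.279 with an estimated correlation). The thymidine kinase gene Tk1 rose 2.61-fold, the thymidylate kinase gene Dtymk 2.02-fold and Dck, deoxycytidine kinase, 1.73-fold. The CTP synthase gene Ctps2 was 1.98-fold lower, with -0.86 in a further probe set, and Rrm2b had -0.55. The call of Rrm2b was lost in 4 of 6 fits with 1 array left out, those without with-putrescine replicates 2 and 3 and no-putrescine replicates 1 and 3 (adjusted p 0.00567 to 0.0933 over the alternatives).

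The CDK inhibitor and p53 target lists were not called. Of 5 CDK inhibitors, Cdkn2c rose 2.07-fold, Cdkn1b fell by 0.63 on the log2 scale and 3 did not pass, with 1 up and 2 down adjusted over the list alone (median 0.13; camera adjusted p = 0.93). Cdkn1a, p21, had a log2 difference of -0.31 (adjusted p = 0.0857, 0.032 to 0.225 over the alternatives), and Cdkn1c, below the level of the other-tissue markers in both groups, did not pass the test (adjusted p = 0.188). Of 23 p53 targets 6 rose, 5 fell and 12 did not pass (6 and 9 adjusted over the list alone; median -0.10; camera adjusted p = 0.867). Polk and Ccng1 rose 2.37-fold and 1.68-fold, and a further probe set of Polk rose by 1.42. The members that fell were Sat1, Plk2 (1.90-fold), Sesn2 (-0.98), Rrm2b and the repair gene Xpc (-0.40). The call of Xpc was lost without with-putrescine replicates 2 and 3 and no-putrescine replicates 1 and 3 (adjusted p 0.00914 to 0.0678 over the alternatives).

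The amino acid response and ATF4 target list moved downward without putrescine. Of 42 measured members 29 fell, 2 rose and 11 did not pass (32 and 2 adjusted over the list alone), and the median log2 difference was -0.71. Besides Trib3, Slc6a9 and Chac1, Ddit3, which encodes the stress transcription factor CHOP, was 3.97-fold lower (-1.99, SE 0.09). The members that rose were the transcription factor gene Atf5 (1.17) and Aldh18a1, the latter from a level below that of the other-tissue markers. Camera gave adjusted p = 9.49e-14, and adjusted p = 0.0734 with an estimated correlation. Atf4 itself had a log2 difference of 0.16 and did not pass the test.

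Endoplasmic reticulum stress genes also fell: 19 of the 25 members of the chaperone and unfolded protein response list were lower, 1 was higher and 5 did not pass (20 and 3 adjusted over the list alone; median -0.59). Herpud1, a component of the degradation pathway of the endoplasmic reticulum, was 4.44-fold lower, Sel1l, of the same pathway, 2.89-fold, and the co-chaperone genes Dnajb9 and Sdf2l1 2.83-fold and 2.74-fold. The member that rose was the translocon gene Sec61b (0.40), whose call was lost without with-putrescine replicate 2 and without no-putrescine replicate 2 (adjusted p 0.00378 to 0.0623 over the alternatives). Camera called the list lower (adjusted p = 4.64e-10), and the call was lost at adjusted p = 0.0834 with an estimated correlation.

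In the autophagy and lysosome list, which camera called lower, 19 of 42 members fell, 1 rose and 22 did not pass (21 and 1 adjusted over the list alone; median -0.22; camera adjusted p = 5.06e-05, and adjusted p = 0.235 with an estimated correlation). Gabarapl1 was 3.26-fold lower, the autophagy gene Wipi1 3.03-fold, the sialidase gene Neu1 2.14-fold and Map1lc3b, an autophagosome marker, 1.82-fold. Hexa rose by 0.32, a call lost in all fits with 1 array left out except that without no-putrescine replicate 2 (adjusted p 0.00873 to 0.0838 over the alternatives). In the NRF2 and antioxidant list 9 of 25 fell, 1 rose and 15 did not pass (11 and 3 adjusted over the list alone; median -0.20). Gss, glutathione synthetase, was 2.78-fold lower, Srxn1, sulfiredoxin, 2.48-fold, Hmox1, heme oxygenase, 2.18-fold and Gclm 1.91-fold. The mitochondrial superoxide dismutase gene Sod2 rose by 0.62. Camera called the list lower at adjusted p = 0.0039, lost at adjusted p = 0.331 with an estimated correlation.

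Among immediate early genes 9 of 22 fell, 3 rose and 10 did not pass (10 and 5 adjusted over the list alone; median -0.27). Besides Atf3, the members with the smallest p were Ier3 (2.82-fold lower), the phosphatase gene Dusp4 (2.69-fold lower) and Fosl2 (2.01-fold lower). The members that rose were Fosb (1.00), Fos (0.62) and Srf (0.43). The call of Srf was lost without with-putrescine replicate 2 and without no-putrescine replicates 1 and 2 (adjusted p 0.00479 to 0.0733 over the alternatives). Camera called the list lower (adjusted p = 0.0134), a call lost at adjusted p = 0.502 with an estimated correlation. The list's median was -0.16 without with-putrescine replicate 1 and also without no-putrescine replicate 1.

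In the oxidative phosphorylation list, which camera called higher, 9 of 25 members rose, 1 fell and 15 did not pass (12 and 1 adjusted over the list alone; median 0.19; camera adjusted p = 0.00346, and adjusted p = 0.181 with an estimated correlation). The complex I subunit genes Ndufb3 and Ndufa5 rose 2.45-fold and 1.78-fold, Ndufa4 1.52-fold and the ATP synthase subunit gene Atp5pd 1.58-fold. Ndufb8 fell by 0.29, a call lost in all fits with 1 array left out except that without with-putrescine replicate 1 (adjusted p 0.001 to 0.0808 over the alternatives). In the extracellular matrix and adhesion list 13 of 43 rose, 3 fell and 27 did not pass (15 and 3 adjusted over the list alone). Besides Thbs1, the collagen genes Col12a1 and Col3a1 rose 3.22-fold and 2.95-fold and the galectin gene Lgals1 1.86-fold. The members that fell were Itga3 (-0.56), Mmp9 (-0.52) and Sparc (-0.31). The call of Mmp9 was lost without with-putrescine replicate 1 and no-putrescine replicates 1 and 3 (adjusted p 0.00343 to 0.0569 over the alternatives). That of Sparc was lost without with-putrescine replicates 2 and 3 and no-putrescine replicates 1 and 3 (0.000761 to 0.0867). The matrix list had a mean difference of 0.29 and a median of 0.06, which was 0.12 without with-putrescine replicate 3 and also without no-putrescine replicate 3. Camera called it higher at adjusted p = 0.0237. The call was lost at adjusted p = 0.175 with an estimated correlation and at 0.0504 over probe sets above the level of the other-tissue markers, the highest of a range from 0.0152. The estimated correlation of the matrix list was -0.006, again below the preset value.

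Lipid and glycolysis lists were not called but held single genes with clear differences. Dgat2, which catalyses the last step of triglyceride synthesis, was 4.10-fold lower, and the acetyl-CoA carboxylase genes Acacb and Acaca were 2.01-fold and 1.38-fold lower. Elovl5 rose 1.29-fold and Fasn by 0.44; the call of Fasn was lost without with-putrescine replicate 2 and no-putrescine replicates 1 and 2 (adjusted p 0.0018 to 0.0567 over the alternatives). In that fatty acid list 2 of 16 members rose, 3 fell and 11 did not pass (3 and 3 adjusted over the list alone; median -0.01; camera adjusted p = 0.596). In cholesterol biosynthesis 3 of 17 rose, 3 fell and 11 did not pass, with the same counts adjusted over the list alone (median 0.09; camera adjusted p = 0.855). Hsd17b7 rose 1.69-fold, Dhcr7 1.47-fold and Hmgcs1 by 0.56, while Lss was 1.88-fold lower, Pmvk 1.76-fold lower and Fdps had -0.44. In glycolysis and hypoxia-responsive genes 6 of 32 rose, 11 fell and 15 did not pass (7 and 12 adjusted over the list alone; median -0.12; camera adjusted p = 0.176). Pdk1, a kinase that restrains pyruvate oxidation in mitochondria, was 3.35-fold lower and the phosphofructokinase gene Pfkp 2.08-fold lower. Adm, adrenomedullin, rose 3.07-fold and the glucose transporter gene Slc2a1 1.79-fold.

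Ribosome biogenesis, translation and heat shock genes were not called as lists. In ribosome biogenesis 11 of 44 rose, 7 fell and 26 did not pass (15 and 10 adjusted over the list alone; median 0.08; camera adjusted p = 0.193), with Bop1 and the RNA polymerase I gene Polr1a each 1.63-fold higher. The further probe sets of Polr1a both rose by 0.73. Dkc1 rose 1.60-fold and Ubtf 1.56-fold. Among translation factors 7 of 35 rose, 3 fell and 25 did not pass (7 and 4 adjusted over the list alone; median 0.09; camera adjusted p = 0.511). Eif4a2 and Eif2b1 rose 1.70-fold and 1.64-fold. Eif4ebp1, a repressor of cap-dependent initiation, was 1.60-fold lower, Eif3b 1.57-fold lower and Eef1e1 had -0.35. The call of Eef1e1 was lost in all fits with 1 array left out except that without with-putrescine replicate 1 (adjusted p 0.00692 to 0.112 over the alternatives). Among cytosolic heat shock proteins 6 of 18 rose, 3 fell and 9 did not pass (8 and 3 adjusted over the list alone; median 0.16; camera adjusted p = 0.342). Hspb1 and Chordc1 rose 1.72-fold and 1.69-fold, Hspa4 and Hspb8 were 1.43-fold and 1.38-fold lower, and Bag3 had -0.35. The call of Bag3 was lost without with-putrescine replicates 1 and 3 and without no-putrescine replicate 3 (adjusted p 0.00319 to 0.0769 over the alternatives).

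Apoptosis, interferon and glycosylation genes moved in both directions. Among apoptosis regulators 4 of 19 rose, 5 fell and 10 did not pass (4 and 6 adjusted over the list alone; median 0.01; camera adjusted p = 0.992). Casp2 rose 2.29-fold, the pore-forming effector gene Bak1 1.84-fold, Fadd by 0.53 and Tnfrsf1a by 0.30. Casp8 was 1.47-fold lower, the survival gene Bcl2l1 1.42-fold lower, and Bmf (-0.54), Cflar (-0.49) and Xiap (-0.46) also fell. The calls of Tnfrsf1a (adjusted p 0.0056 to 0.0874 over the alternatives) and Xiap (0.00677 to 0.109) were lost without replicates 1 and 2 of either group. That of Cflar was lost without any of the with-putrescine replicates and without no-putrescine replicate 1, where its log2 difference was -0.31 (0.0104 to 0.0995). Among interferon-stimulated genes 3 of 21 rose, 4 fell and 14 did not pass (4 and 4 adjusted over the list alone; camera adjusted p = 0.992). The immunoproteasome gene Psmb8 rose 2.42-fold, Bst2 by 0.27 and B2m by 0.26. Oasl was 2.18-fold lower, Stat2 1.72-fold lower, Ddx58 1.43-fold lower and Parp14 had -0.40. Bst2 lost its call in all fits with 1 array left out except that without no-putrescine replicate 1 (adjusted p 0.00182 to 0.118 over the alternatives), B2m in all 6 (0.000765 to 0.115), and both also after quantile normalization. Parp14 lost its call without replicate 2 of either group (0.00973 to 0.0652). The interferon list's median was 0.01 while its mean (-0.01) and camera pointed downward. Among N-glycosylation enzymes 6 of 27 rose, 6 fell and 15 did not pass (6 and 7 adjusted over the list alone; median 0.00; camera adjusted p = 0.659). Mgat4b and Mgat2, which set antenna branching, rose 1.47-fold and 1.36-fold, and the sialic acid synthesis genes Gne and Nans were 1.48-fold and 1.45-fold lower.

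The control lists were not called. Of 15 reference genes 4 rose, 1 fell and 10 did not pass, with the same counts adjusted over the list alone (median 0.13; camera adjusted p = 0.0951). Tfrc, Ywhaz (1.65-fold), Hprt1 (1.61-fold) and B2m rose, and Gusb was 1.57-fold lower. This list was called with a trended variance (adjusted p = 0.0288, in a range of 0.0288 to 0.169). Of 20 measured markers of other tissues 2 rose, 2 fell and 16 did not pass, again with the same counts adjusted over the list alone (median -0.01; camera adjusted p = 0.659). Cd68, a macrophage marker that is also a lysosomal protein of other cells, was 7.14-fold lower, and the muscle actin gene Actc1 1.58-fold lower. Apoa2 rose 1.62-fold. Lyz passed the test with levels of 2.97 and 3.42, both below the list's own median level of 3.82, so no fold is given. The call of Actc1 was lost without with-putrescine replicates 1 and 2 and no-putrescine replicates 1 and 3 (adjusted p 0.0119 to 0.118 over the alternatives).

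**Figure D3:**
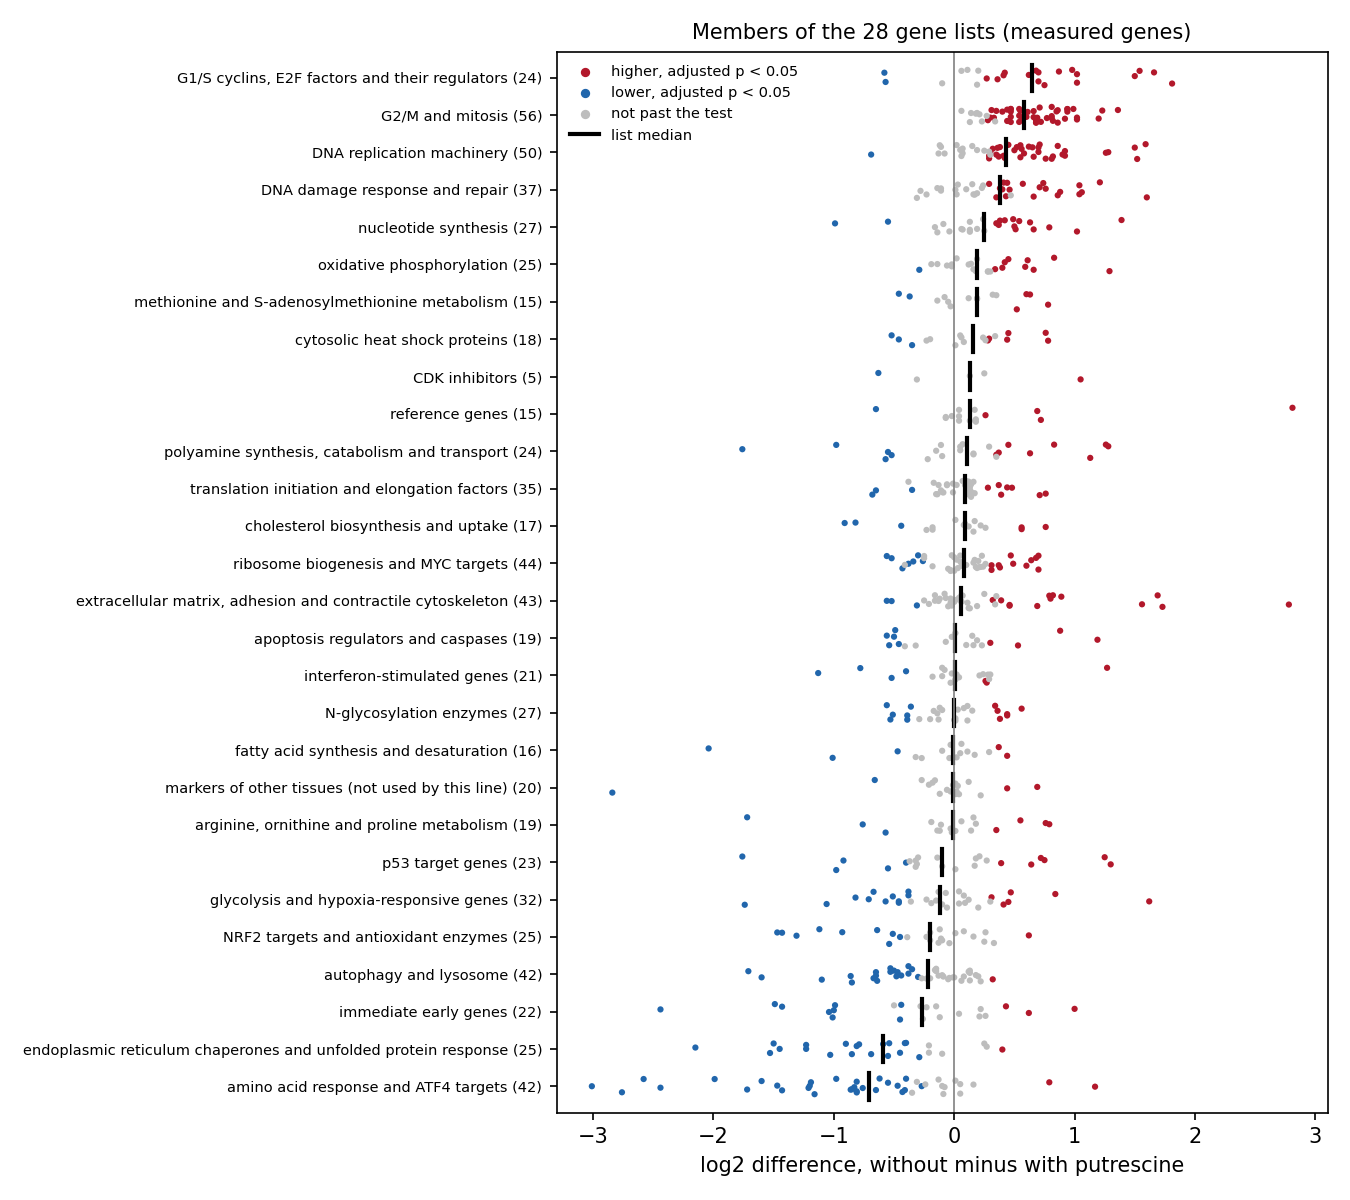
Log2 difference without minus with putrescine for each measured member of the 28 gene lists, with the number of measured members in brackets. Red and blue points are members higher or lower at adjusted p under 0.05, grey points did not pass, and black bars are list medians, from 0.65 for the G1/S list to -0.71 for the ATF4 target list.

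In all, camera with its preset correlation called 12 of the 28 lists, 7 higher and 5 lower. With an estimated correlation it called 0, the lowest adjusted p being 0.0734, with 7 lists at an unadjusted p under 0.05. That setting also tests with fewer degrees of freedom, so the losses are not due to inter-gene correlation alone. In the splits of the 6 arrays that mixed the groups, the preset correlation called 5 to 8 lists. These splits still hold part of the real difference, so that is not a rate of false calls. In fry, which asks only whether a list's own members changed, 22 lists passed the directional test and all 28 the mixed test. The directional test asks for an average change other than 0, not for members that move together. N-glycosylation passed it (fry adjusted p = 0.0381) with 6 members up and 6 down.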

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

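The list alternative without members shared with the ATF4 list was chosen after seeing the data; it called 12 lists, as in the reported test. The count of 7240 probe sets stayed within 1.5 times under the variance, scaling and filter settings, from 5007 (2642 up, 2365 down) with 1 probe set per gene, where fewer probe sets were tested, to 8065 with a trended and robust variance, and from 5810 to 6237 with 1 array left out. Rises then ranged from 3116 to 3376 and falls from 2685 to 2892. Rises made up 51.2% of calls after quantile normalization and 56.2% after median centring, against 54.1% as reported. Stricter thresholds gave other counts by construction: 4456 (2375 up, 2081 down) at adjusted p under 0.01, 3115 (1636 up, 1479 down) with at least 1.5-fold change, and 3150 (1655 up, 1495 down) at unadjusted p under 0.05 with at least 1.5-fold change. A two-sample test without moderation called 5217. The number of called lists was 12 with each array left out, 11 over probe sets above the level of the other-tissue markers and 13 with a trended variance. It was 0 with an estimated correlation, 22 with directional fry and 28 with mixed fry, which tests another hypothesis.

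The replicate numbers did not pair the cultures: same-numbered arrays had residual correlations of 0.045, -0.101 and -0.020, and no array correlated best with its own number. With the replicate block 6408 probe sets differed, 3457 up and 2951 down, of which 6201 were among the 7240, and 12 lists were called. Of 170 genes followed, 160 kept their side of the threshold with the block, 166 after quantile normalization and 170 after median centring. The block ended the calls of Atp13a3, Slc25a15, Bag3, Ndufb8, Eef1e1, Tnfrsf1a, Hexa, Sparc, Bst2 and B2m, at adjusted p from 0.05 to 0.101.

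Medians near 0 changed sign in lists that were called by camera under none of these settings; the cause was not tested. After median centring the arginine and fatty acid lists were both at 0.01. Without the dimmest 25% of probe sets the interferon list was at -0.01, and above the level of the other-tissue markers it was at -0.02 and the CDK inhibitors at -0.09. With 1 array left out the medians ran from -0.03 to 0.09 for apoptosis, -0.05 to 0.04 for arginine, -0.04 to 0.05 for fatty acids and -0.04 to 0.03 for interferon. Other lists not called also had medians that moved by over 1.5 times in these fits: 0.04 to 0.16 for polyamines, 0.02 to 0.16 for CDK inhibitors, -0.15 to 0 for p53 targets, 0.11 to 0.19 for methionine, -0.16 to -0.07 for glycolysis and 0.05 to 0.14 for cholesterol. The polyamine median was 0.22 without the dimmest 25% of probe sets and 0.29 above the level of the other-tissue markers, where that of the p53 targets was -0.05 and that of the other-tissue markers -0.12. After quantile normalization the medians were 0.04 for ribosome biogenesis and 0.05 for cholesterol, and with array weights that of apoptosis was 0.10. No pseudocount was varied, since the table is on a log scale, and the lists were not rerun for 1 probe set per gene, which camera already used. Among the genes named, Arg1, Arg2, Lyz and Cdkn1c lay under the level of the other-tissue markers, 3.82, in both groups and Aldh18a1 with putrescine; the lowest 25% of probe sets lay under 3.36.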

Other observations

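The tests of the array scaling for the 4 genes below, those by quantile normalization and the split counts for probe sets were chosen only after the result was seen. The margin required in the test of replication against G2/M genes, and the view that median centring decides nothing here, were also settled after the values were seen. The other tests were written down before.

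Ypel3, Klhl24, Ccng2 and Gabarapl1, which are known to respond to FOXO transcription factors, were lower without putrescine, by -2.73, -1.97, -1.73 and -1.71 on the log2 scale (limma adjusted p = 1.58e-05, 1.99e-05, 6.1e-05 and 4.54e-05). Quantile normalization left the 4 past the threshold with a median of -1.86. It changed calls of other genes (7002 of its 7267 probe sets were among the 7240). The median of the 4 was -1.84 after median centring. The array medians already lay between 4.92 and 4.98, so neither step could move such large differences much. The falls hold relative to the typical probe set, with a median log2 difference of 0.007 over all probe sets. Scaling already done by the authors cannot be undone here, so its part in the falls was not tested. Lower FOXO activity without putrescine is a candidate explanation: of 19 other FOXO-responsive genes 15 were measured, 7 fell, 0 rose and 8 did not pass, with a median of -0.26. The falls were Fbxo32 (-1.41), Insr (-1.20), Mxd4 (-1.17), Pnrc1 (-0.86), Pdk4 (-0.50), Bcl6 (-0.49) and Txnip (-0.32). Among the 8 that did not pass, Trim63 (0.37) and Foxo4 (0.32) were above 0. The others of the 8 lay between -0.26 (Foxo3) and -0.04 (Rictor). These counts hold for this list only. It did not include Sod2, Cdkn1b, Cat and Bcl2l11, also known to respond to FOXO factors, which were measured in other lists here. Sod2 rose (0.62), Cdkn1b fell (-0.63) and Cat did not pass (-0.10). The groups overlapped for Bcl2l11 (6.74 to 7.03 with and 6.99 to 7.16 without putrescine). The list's median ran from -0.32 to -0.18 with 1 array left out. Camera gave adjusted p = 0.00168, and adjusted p = 0.10 with an estimated correlation, and FOXO protein activity was not measured here, so the hypothesis stays open.

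The fall of the ATF4 target list cannot be put down to a single culture, since its median was -0.70 in the weakest fit with 1 array left out. After quantile normalization the list was still called by camera with its preset correlation, with a median of -0.74 (-0.69 after median centring). On the deposited values that call was lost with an estimated correlation (camera adjusted p = 0.0734). As above, renormalizing could move little, and scaling already done by the authors was not tested. A stronger amino acid shortage in the putrescine-fed cultures by day 3 may account for the fall of the list. The aminoacyl-tRNA synthetase members had a median of -0.71, with 8 of 10 lower and 0 higher. These genes belong to the list itself, and other inputs to ATF4 would lower them too, including relief of endoplasmic reticulum stress. Amino acid levels were not analysed here, so the source of the difference stays open.

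The DNA replication list was likewise still called higher by camera, with its preset correlation, after quantile normalization. Its median was then 0.41, and 0.45 after median centring. On the deposited values the call was lost with an estimated correlation (camera adjusted p = 0.103). Scaling already done by the authors was again not tested. A larger share of cells in late G1 and S phase predicts that replication genes rise more than G2/M genes. The mean replication level minus the mean G2/M level instead changed by -0.11 (SD 0.052 with and 0.059 without putrescine, n = 3). Replication genes thus did not rise more than G2/M genes, although the nearest arrays of the groups almost met (-0.794 and -0.79). An earlier rule, which asked for a gap above the larger SD, left the question undecided. List levels do not measure shares of cells, so a larger late G1 and S share is not excluded. A rise of all proliferation genes might be involved. Its prediction asked for G2/M and ribosome biogenesis medians above 0, without overlap of the groups' mean levels. This was met, with medians of 0.58 and 0.08. Ribosome biogenesis levels were 9.811 to 9.834 without and 9.695 to 9.757 with putrescine. A condition outside that prediction set aside a median this near 0. The ribosome biogenesis members also went both ways, so the question stays open. No direct count of cells per cycle phase was analysed here, and an effect of putrescine removal on cycle genes without any shift in phase was not tested. The design text says that growth, viability and cell cycle were followed, but their values were not given in the sources used here. Growth-related explanations of the cycle and ATF4 changes could therefore not be tested.

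The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the probe sets that differed, rose and fell, 1 of 10 splits, the real one, gave as many (7240, 3915 and 3325), and the highest of the others gave 0 in each case, with 458 to 943 probe sets at unadjusted p under 0.05. For the gene lists the real split gave 12 and the highest of the others 8, with 5 to 8 lists called in every split that mixed the groups under the preset correlation. A mixed split keeps part of the real difference between its sides and moves the rest into the residual variance. Few calls were therefore built in: the 458 to 943 lie below the 1485 expected by chance at unadjusted p under 0.05. Neither these counts nor the 5 to 8 lists measure false calls.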
